A study of Homo sapiens with 30 samples.

How the data were processed

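RNA from THP-1 cells, an established human monocytic leukaemia line, was measured on 30 Affymetrix 3-prime expression arrays. The labels state that the cells were first differentiated for 24 h with 82 nM phorbol 12-myristate 13-acetate (PMA), which turns them into macrophage-like cells. They were then kept without particles or with 10 or 100 µg/ml of multi-walled carbon nanotubes (MWCNT) or titanium dioxide nanobelts (TiO2-NB) for 1 or 24 h, which gives 10 groups of 3 arrays. The deposited values are log2 probe set intensities, which the authors background-corrected, normalized between arrays and summarised by RMA per the submitters' processing notes, which give no version. The values ran from 1.89 to 14.42, array medians lay between 6.35 and 6.46, and the values were not normalized again. An array gives no read depth, and the number of arrays limits the precision.

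Of 22277 probe sets, 62 were spike-in or control features, 19064 of the others matched 1 gene, 1043 several genes and 2108 none. Probe sets of several genes or of none were left out. A probe set was kept when it lay above the 25th percentile of the array on at least 3 arrays, which 17526 did. The kept probe set with the highest mean stood for its gene, which left 10050 genes, 3419 of them with several kept probe sets. The files give no genome positions.

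Genes were tested in R 4.3.3 with limma 3.58.1, as 1 fit of all 30 arrays with 10 group means and 20 residual degrees of freedom. The moderated two-sided test was adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. With no true change, about 502.5 of the 10050 genes would have an unadjusted p under 0.05. Each exposure was compared with the control of the same time, the materials with each other at each dose and time, 100 with 10 µg/ml within each material and time, the 24 h control with the 1 h control, and the response at 24 h with that at 1 h. A test of any exposure at each time used the F statistic. Errors of log2 fold changes are standard errors of the fit, and errors of levels are SDs of 3 arrays.

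The comparisons, the tests, the gene lists, most of the alternatives and the rule for naming genes were chosen before the data were examined. The rule took the 8 largest rises and falls of each comparison with control and of the control time comparison, and the 6 largest of each direction in the other comparisons. Outside the comparison of responses at both times, only genes whose arrays did not overlap between the groups qualified. It also took up to 4 called members per list with the largest change, and HMOX1, IL1B, CXCL8, TNF, MT2A, CCL2, CDKN1A, ABCG1 and HMGCS1. Genes named outside this rule are said to be so where they appear. The 26 gene lists covered inflammatory cytokines and chemokines, NF-kappaB feedback targets, inflammasome and pyroptosis, NRF2 antioxidant targets, metallothioneins and zinc export, heat shock response, unfolded protein and integrated stress response, p53 and DNA damage targets, DNA replication, mitosis, cholesterol biosynthesis and uptake, LXR targets and lipid efflux, lysosome, autophagy, hypoxia and glycolysis, oxidative phosphorylation, interferon-stimulated genes, scavenger and phagocytic receptors, promonocyte and monocyte markers, macrophage differentiation markers, matrix remodelling and adhesion, immediate early genes, ribosome biogenesis, and epithelial, lymphocyte and fibroblast markers. Lists were tested with camera of limma, which compares a list with all other genes, at a preset correlation of 0.01 between genes and again with a correlation estimated from the data. Its p was adjusted over 208 tests for the exposures and over 52 for the materials at 100 µg/ml. For the control time comparison it was adjusted over the 26 lists.

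The labels number the arrays of each group, and whether equal numbers mark a shared culture or day was checked. Of 60 pairs of equally numbered arrays, 38 had deviations from their group means that correlated above 0.1 and 21 correlated negatively, from -0.53 to 0.73, and 18 of the 30 arrays correlated best with arrays of their own number. The numbers did not pair the arrays throughout, but they did in part. At 1 h every such pair among the control, both MWCNT groups and 100 µg/ml TiO2-NB correlated (0.33 to 0.73), while with 10 µg/ml TiO2-NB the pairs of replicate 3 did (0.38 to 0.45) and those of replicates 1 and 2 were negative. At 24 h every such pair correlated above 0.1 among the control and the 10 µg/ml groups, and between the 100 µg/ml groups. Across these sets the pairs of replicates 1 and 3 were negative, and those of replicate 2 ran from -0.06 to 0.39. The numbers were not used in the fit, and a fit with them as a block over all groups is among the alternatives. Where equally numbered arrays deviated together, the fit without them counted the shared deviation as spread and may call fewer genes. The block also joins groups whose equally numbered arrays correlated negatively, so it is no clean paired fit.

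The calls were tested on simulated data: each gene kept its own spread around a flat level, and 50 genes of each size of change were altered in the exposed group. Deviations shared by genes or by arrays were not simulated. For 100 µg/ml of MWCNT at 24 h limma found 86% of genes changed 1.5-fold and 98% of genes changed 2-fold, with 6 false calls. For 100 µg/ml of TiO2-NB at 24 h the shares were 76% and 96%, with 10 false calls.

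Alternatives were no filter and a stricter filter on dim probe sets, the replicate block, a fit of only the arrays of the groups compared, centring each array on its median, an intensity trend with a robust prior, every probe set or the mean of the probe sets of a gene, an estimated correlation in camera, and leaving out each array in turn. Chosen after seeing the data were cyclic loess normalization in 2 forms, a fit with the first residual component of each time as a covariate, that covariate together with the estimated correlation in camera, and a fit without 10 arrays that stood apart.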

Results

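Transcript levels were compared in PMA-differentiated THP-1 macrophage-like cells kept with MWCNT, TiO2-NB or no particles, with 3 arrays for each of the 10 combinations of material, dose and time. MWCNT are tube-shaped carbon fibres and TiO2-NB are long ribbon-shaped particles of titanium dioxide. The series asks how cells respond to both at a low and a high dose, early and late. Values are log2 RMA intensities, the median residual SD of a gene was 0.128, and n = 3 arrays per group throughout. Correlations between arrays were 0.963 or higher over all pairs and 0.991 or higher within groups. The first principal component took 61.9% of the variance and parted the 1 h from the 24 h arrays, and the second and the third took 8.25% and 6.91%. In each group 1 of the 3 arrays lay apart from the others on the first component of the values around the group means, which took 43.1% of that variance at 1 h and 49.9% at 24 h. Deviations of 3 arrays from their own mean cancel out, so 1 of the 3 always lies opposite the others on a component.

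**Figure D1:**
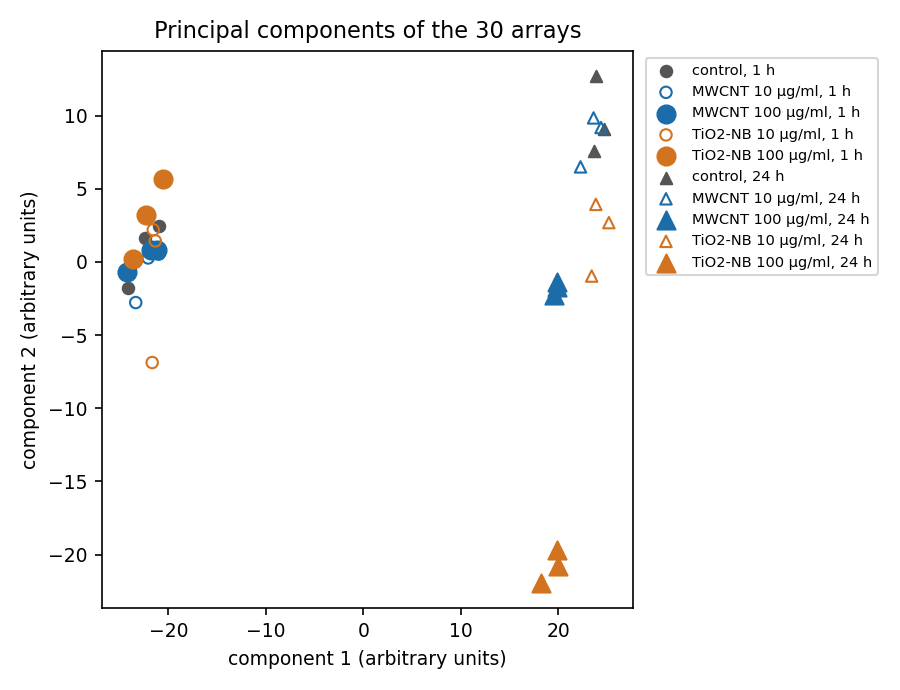
Scores of the 30 arrays on the first and second principal components of the tested genes, in arbitrary units, with circles for 1 h, triangles for 24 h, colours for the material, open symbols for 10 µg/ml and large symbols for 100 µg/ml. The first component, with 61.9% of the variance, parts the times.

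**Figure D2:**
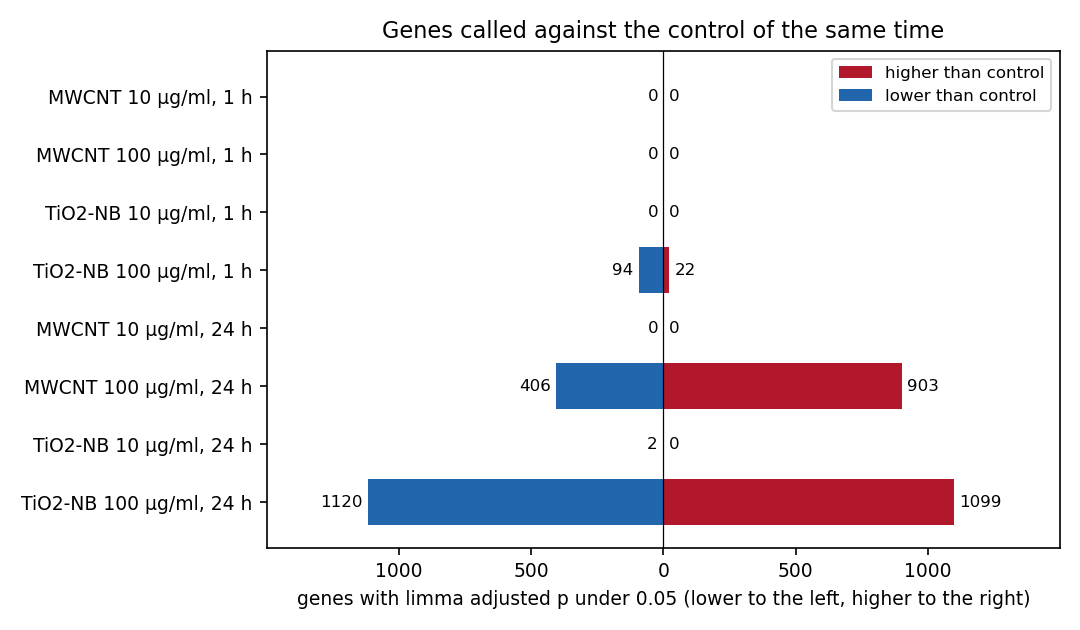
Number of genes called by limma at an adjusted p under 0.05 in each exposure against the control of the same time, with higher genes to the right and lower genes to the left. The large counts are those of 100 µg/ml at 24 h, with 903 higher and 406 lower genes for MWCNT and 1099 higher and 1120 lower genes for TiO2-NB.

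After 24 h with 100 µg/ml MWCNT the cells carried more mRNA of chemokines, interferon-stimulated genes and cell cycle genes than control cells. Of these groups only the chemokines kept their list call with an estimated correlation (adjusted p = 3.82e-05, against adjusted p = 0.208 for interferon genes, 0.335 for DNA replication and 0.509 for mitosis). TNFAIP6 (probe set 206025_s_at), an NF-kappaB-induced hyaluronan-binding protein, rose from a log2 level of 5.90 ± 0.41 to 8.82 ± 0.08, a log2 fold change of 2.92 ± 0.40 (adjusted p = 2.68e-05 by limma). CCL4 (204103_at), a chemokine that attracts monocytes and T cells, rose by 2.39 ± 0.23, LAMP3 (205569_at), a lysosomal membrane protein of mature dendritic cells, by 2.31 ± 0.28, and VCAM1 (203868_s_at), an adhesion molecule, by 2.31 ± 0.25. NPTX1 (204684_at), a neuronal pentraxin, changed by -3.31 ± 0.28 and CYP1B1 (202436_s_at), a cytochrome P450 induced through the aryl hydrocarbon receptor, by -2.44 ± 0.25. For all of these genes the 3 exposed arrays lay on 1 side of the 3 control arrays, which the rule for naming required. The same held for 30% of all tested genes. In all, 1309 of 10050 genes were called, 903 higher and 406 lower, and 378 of them changed at least 1.5-fold. Without replicate 1 of the 24 h control 778 genes were called. With each array centred on its median the total was 1320 but the higher genes numbered 726.

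Of the 24 measured inflammatory cytokines and chemokines 17 rose and none fell with MWCNT at this dose and time, or 18 when adjusted over the list alone, with a median log2 fold change of 0.73. They included CCL4, EBI3 (2.06 ± 0.52), a subunit of interleukins 27 and 35, CCL8 (1.94 ± 0.26) and CXCL10 (1.83 ± 0.20), a chemokine induced by interferon. Camera called the list as higher than other genes (adjusted p = 2.06e-13), also with an estimated correlation (adjusted p = 3.82e-05). Of the 17 NF-kappaB feedback targets 13 rose, also over the list alone, among them GCH1 (1.32 ± 0.20), which starts tetrahydrobiopterin synthesis, TRAF1 (1.12 ± 0.17), an adaptor of TNF receptors, and TNFAIP3 (0.87 ± 0.12), which limits NF-kappaB signalling. The median of that list was 0.61 (adjusted p = 4.26e-13, but adjusted p = 0.091 with an estimated correlation). CCL2 rose by 1.06 ± 0.22, and TNF (0.65 ± 0.21, adjusted p = 0.0367) and CXCL8 (0.39 ± 0.11, adjusted p = 0.0155) passed the test with all arrays. TNF failed it without replicates 1 or 2 of the control or without any 1 exposed array (adjusted p from 0.0549 to 0.226, and from 9.71e-06 to 0.226 over all alternatives). CXCL8 failed it without replicates 1 or 2 of the control or replicate 1 of the exposed group (adjusted p from 0.0509 to 0.101, and from 0.00063 to 0.101 over all alternatives). IL1B (0.10 ± 0.20), HMOX1 (0.13 ± 0.11), MT2A (0.22 ± 0.11), CDKN1A (-0.24 ± 0.10), ABCG1 (-0.14 ± 0.32) and HMGCS1 (0.25 ± 0.11) were not called. IL1B lay at 13.58 ± 0.21 in the 24 h control, near the highest value of all arrays, 14.42.

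Interferon-stimulated genes, which code for antiviral proteins, were higher with MWCNT: 20 of 28 rose and none fell, or 23 when adjusted over the list alone. IFIT1 rose by 1.65 ± 0.28, IFI44 by 1.53 ± 0.20, IFI44L by 1.47 ± 0.20 and MX1 by 1.45 ± 0.22. The median of the list was 0.74, with an adjusted p of 8.96e-20 that was lost with an estimated correlation (adjusted p = 0.208). Of 23 DNA replication genes 22 rose, or 23 over the list alone, with a median of 0.93. TYMS, the thymidylate synthase, rose by 1.49 ± 0.23, CCNE2, a cyclin of S phase entry, by 1.45 ± 0.29, and RRM2, a subunit of ribonucleotide reductase, by 1.38 ± 0.24. Of 27 mitosis genes 21 rose, or 23 over the list alone, with a median of 0.71, among them NDC80 (1.31 ± 0.22), a kinetochore protein, and CDK1 (1.16 ± 0.21), the mitotic kinase. The replication list had an adjusted p of 6.14e-19 (adjusted p = 0.335 with an estimated correlation), and the mitosis list had 2.35e-14 (adjusted p = 0.509 with an estimated correlation). Part of the variation of these lists ran with the arrays that lay apart: the estimated correlation between their genes fell from 0.715 to 0.315 for replication and from 0.644 to 0.187 for mitosis with the residual components as covariates. With these covariates the adjusted p was 0.0104 for each with an estimated correlation, and 0.152 for the interferon list, but the covariates were taken from the same residuals.

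Smaller shifts with MWCNT were seen in 3 further lists. Of 19 ribosome biogenesis genes 10 rose, or 14 over the list alone, with a median of 0.28, led by WDR12 (0.53 ± 0.08), and the adjusted p was 1.87e-08 (adjusted p = 0.401 with an estimated correlation). Of 18 cholesterol genes 5 rose and 1 fell, or 9 and 1 over the list alone, with a median of 0.23. TMEM97, a sterol-regulated membrane protein, rose by 1.06 ± 0.20, LSS by 0.49 ± 0.10, and INSIG1, which holds the sterol sensor in the endoplasmic reticulum, changed by -0.44 ± 0.10 (list adjusted p = 0.00119, adjusted p = 0.315 with an estimated correlation). Of 27 oxidative phosphorylation genes 4 rose, or 7 over the list alone, with a median of 0.07 (adjusted p = 0.017, adjusted p = 0.768 with an estimated correlation). That last call was also lost with median centring, with either form of cyclic loess and with the stricter filter (adjusted p from 0.0764 to 0.115, and from 0.00675 to 0.115 over the alternatives that kept the preset correlation).

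The remaining lists were not called by camera for MWCNT. Among NRF2 antioxidant targets 8 of 26 were higher and 2 lower, or 9 and 2 over the list alone (adjusted p = 0.27). GCLM, which limits glutathione synthesis, rose by 0.78 ± 0.19. Scavenger and phagocytic receptors had 1 higher and 5 lower of 22, the same over the list alone, with FCGR2B at -1.0 ± 0.19 and STAB1 at -0.85 ± 0.14 (list adjusted p = 0.0632). LXR targets had 4 higher of 12, such as NR1H3, the LXR alpha receptor, at 0.88 ± 0.18, and macrophage differentiation markers had 3 lower of 18. Lysosomal genes had 2 higher and 4 lower of 28. Unfolded protein response genes and matrix genes each had 2 higher and 2 lower, of 25 and 21. Inflammasome and p53 lists each had 2 higher and 1 lower, of 14 and 15, and immediate early genes had 2 higher of 26. Autophagy, hypoxia and monocyte lists each had 1 higher and 1 lower, and the heat shock list had 1 higher. Metallothioneins, epithelial markers and lymphocyte markers had 0 called genes by limma. Of the fibroblast markers 1 of 8 rose, PDGFRA, a growth factor receptor (1.08 ± 0.15).

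**Figure D3:**
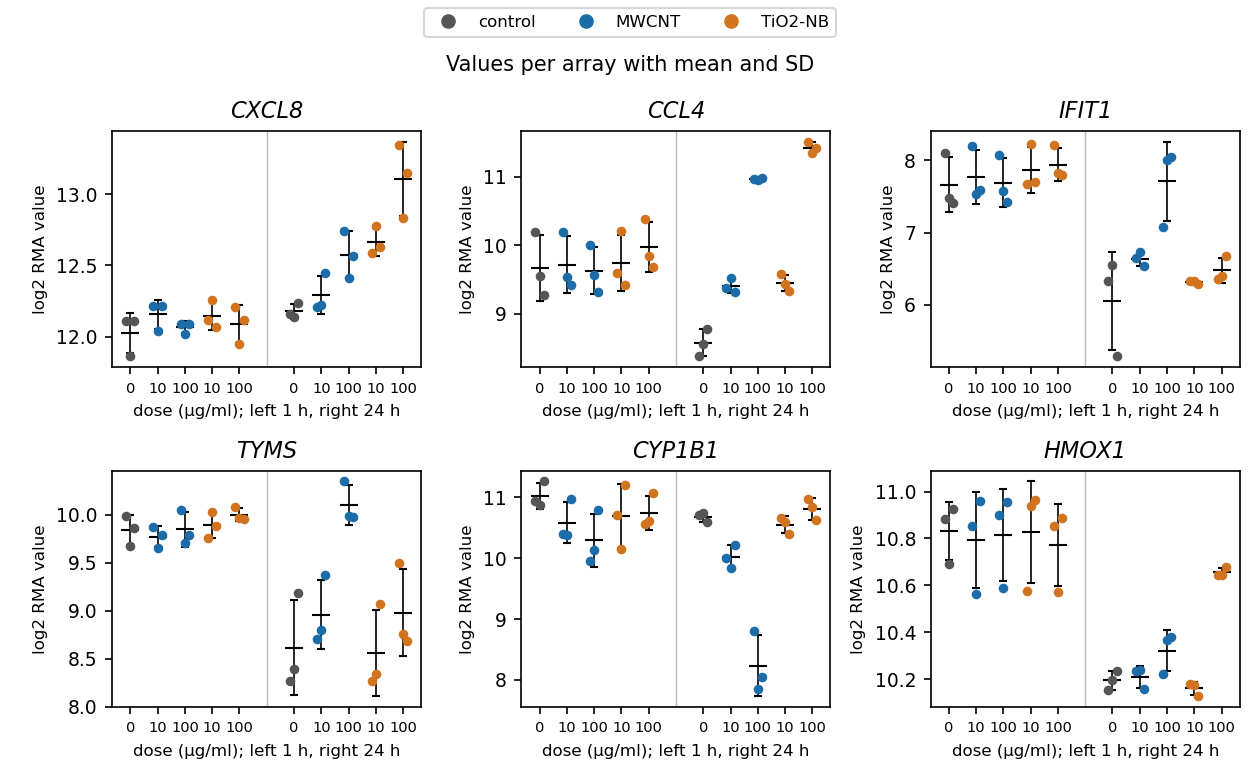
Log2 RMA values of 6 genes on each array, by dose in µg/ml, with 1 h to the left and 24 h to the right, and with the mean and SD of 3 arrays for each group. CCL4 and CXCL8 are highest with 100 µg/ml TiO2-NB at 24 h, IFIT1 and TYMS are above the 24 h control with MWCNT at 100 µg/ml, and CYP1B1 falls to 8.24 there.

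After 24 h with 100 µg/ml TiO2-NB, 2219 genes were called, 1099 higher and 1120 lower, of which 592 changed at least 1.5-fold. CCR7 (206337_at), the receptor that guides dendritic cells to lymph nodes, rose by a log2 fold change of 3.37 ± 0.17, from 4.34 ± 0.17 to 7.71 ± 0.36 (adjusted p = 1.79e-12). CCL4 rose by 2.85 ± 0.23, the neutrophil-attracting chemokines CXCL2 (209774_x_at) by 2.80 ± 0.18 and CXCL1 (204470_at) by 2.77 ± 0.22, and TNFAIP6 by 2.65 ± 0.40. ANKRD11 (219437_s_at), a chromatin regulator, changed by -2.04 ± 0.20, NAA15 (219158_s_at), a subunit of an N-terminal acetyltransferase, by -1.88 ± 0.29, and GJA1 (201667_at), the gap junction protein connexin 43, by -1.85 ± 0.29. TM7SF3 (217974_at) changed by -1.84 ± 0.19 and IL6R (205945_at), the interleukin 6 receptor, by -1.82 ± 0.32. In these genes the exposed and control arrays did not overlap, which the rule for naming required. The same held for 33.3% of all tested genes. When only the arrays of the groups compared were fitted, 1304 genes were called. With each array centred on its median 1267 of 2233 called genes were higher.

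Of 24 cytokines and chemokines 16 rose with TiO2-NB and none fell, or 17 over the list alone, with a median of 0.89 (adjusted p = 6.75e-15, and adjusted p = 3.01e-05 with an estimated correlation). CXCL3 rose by 2.52 ± 0.15, TNF by 1.48 ± 0.21, CCL2 by 1.54 ± 0.22 and CXCL8 by 0.93 ± 0.11. IL1B was not called (0.29 ± 0.20), but its 24 h control level of 13.58 ± 0.21 limits the rise that could be seen. Of 17 NF-kappaB feedback targets 15 rose, also over the list alone, with a median of 0.78, among them TRAF1 (1.54 ± 0.17), TNFAIP3 (1.38 ± 0.12) and TNFAIP2 (1.31 ± 0.10). That list had an adjusted p of 6.75e-15 (adjusted p = 0.0597 with an estimated correlation). Immediate early genes, which are transcribed within minutes of a stimulus, had 10 higher and 1 lower of 26, or 14 and 1 over the list alone. NR4A2 (2.60 ± 0.47) and NR4A3 (2.25 ± 0.26), orphan nuclear receptors, and EGR3 (1.22 ± 0.35) rose. The list's adjusted p was 0.00149 (adjusted p = 0.401 with an estimated correlation).

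Of 26 NRF2 antioxidant targets 9 rose and 1 fell with TiO2-NB, or 10 and 1 over the list alone, with a median of 0.23. SLC7A11, the cystine importer, rose by 1.53 ± 0.25, GCLM by 1.04 ± 0.19, TXNRD1, thioredoxin reductase, by 0.93 ± 0.08, and HMOX1, haem oxygenase, by 0.46 ± 0.11. The list's adjusted p was 0.00292 (adjusted p = 0.642 with an estimated correlation). Scavenger and phagocytic receptors had 7 lower and 1 higher of 22, or 10 and 2 over the list alone, with a median of -0.21 (adjusted p = 0.00393, adjusted p = 0.37 with an estimated correlation). MERTK, a receptor for the uptake of dying cells, changed by -1.15 ± 0.20, MSR1, a scavenger receptor, by -0.94 ± 0.21, FCGR2B by -0.92 ± 0.19 and CD163, a haemoglobin scavenger receptor, by -0.82 ± 0.15. Of 18 cholesterol genes 5 were lower and 1 higher, or 7 and 1 over the list alone, with a median of -0.12. LSS rose by 0.65 ± 0.10 while MSMO1 changed by -0.62 ± 0.07, SC5D by -0.55 ± 0.09 and HSD17B7 by -0.50 ± 0.08, all enzymes of sterol synthesis. The adjusted p of 0.0258 became 0.0704 with the stricter filter, ranged from 0.0119 to 0.0704 over the alternatives with the preset correlation, and was lost with an estimated correlation (adjusted p = 0.642). Mitosis genes (median 0.31, 4 of 27 higher, 1 over the list alone) and DNA replication genes (median 0.34, 2 of 23 higher, also over the list alone) had adjusted p values of 0.0109 and 0.0119. Both were lost with an estimated correlation (adjusted p = 0.997 each).

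The remaining lists were not called by camera for TiO2-NB. The unfolded protein and integrated stress response list went both ways, with 10 higher and 6 lower of 25 (adjusted p = 0.324). ATF3, a stress-induced transcription factor, rose by 1.35 ± 0.15, while PDIA4 (-0.71 ± 0.13) and SDF2L1 (-0.70 ± 0.16), folding factors of the endoplasmic reticulum, fell. Lysosomal genes had 8 higher and 3 lower of 28, with ATP6V1H, a proton pump subunit, at 0.59 ± 0.08 and NEU1, a sialidase, at 0.58 ± 0.07 (list adjusted p = 0.214). Autophagy genes had 5 higher of 19, such as the receptor OPTN at 0.58 ± 0.10 (list adjusted p = 0.164). Interferon-stimulated genes had 4 higher and 1 lower of 28 (adjusted p = 0.266). Macrophage differentiation markers had 3 higher and 4 lower, hypoxia genes 4 higher and 2 lower, oxidative phosphorylation genes 4 higher and 1 lower, and matrix and p53 genes each 2 higher and 3 lower. Ribosome biogenesis had 3 higher and 1 lower, heat shock 3 higher, LXR targets 2 higher, the inflammasome and monocyte lists each 2 lower, metallothioneins and zinc export 1 lower (SLC30A1, a zinc exporter, -0.87 ± 0.18) and fibroblast markers 1 higher. Epithelial and lymphocyte markers had 0 called genes by limma. MT2A (-0.09 ± 0.11), CDKN1A (0.04 ± 0.10), ABCG1 (-0.10 ± 0.32) and HMGCS1 (-0.10 ± 0.11) were not called.

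**Figure D4:**
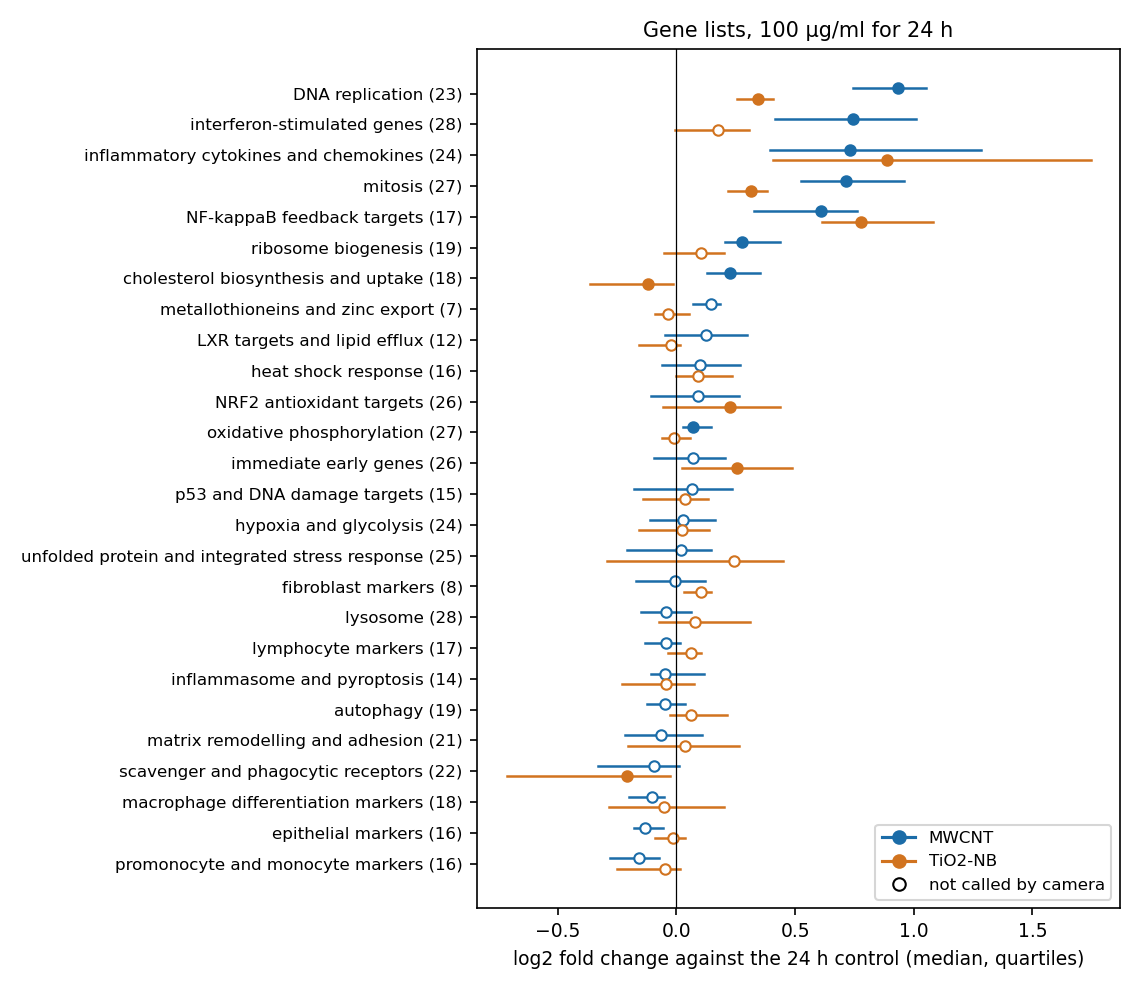
Median log2 fold change and quartiles of the measured members of each fixed gene list after 24 h with 100 µg/ml, for MWCNT and TiO2-NB, with the number of measured genes in brackets and filled points for lists called by camera at the preset correlation. DNA replication (0.93 and 0.34) and interferon-stimulated genes (0.74 and 0.17) lie higher with MWCNT, and cytokines (0.73 and 0.89) lie near each other.

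The materials were compared directly to ask whether they differ at the same dose and time. At 100 µg/ml and 24 h 2505 genes differed, 1411 higher with MWCNT and 1094 higher with TiO2-NB, and 495 differed at least 1.5-fold. With median centring 2776 genes differed, and 1010 of them were higher with MWCNT. TM7SF3 was higher with MWCNT by 1.80 ± 0.19, NAA15 by 1.76 ± 0.29, VCAM1 by 1.75 ± 0.25 and CEMIP, a hyaluronan-degrading protein, by 1.73 ± 0.27. NPTX1 (-2.95 ± 0.28), CYP1B1 (-2.58 ± 0.25), the transcription factor FOXF1 (-2.29 ± 0.23) and NR4A2 (-2.26 ± 0.47) were lower with MWCNT than with TiO2-NB. Of 28 interferon-stimulated genes 21 were higher with MWCNT and none lower, or 24 over the list alone, with a median difference of 0.60, led by IFI44L (1.59 ± 0.20) and IFI44 (1.40 ± 0.20). DNA replication (16 of 23 higher, 18 over the list alone, median 0.65) and mitosis (11 of 27 higher, also over the list alone, median 0.45) were also higher with MWCNT. Of 18 cholesterol genes 12 were higher and 1 lower, or 13 and 1 over the list alone, with TMEM97 at 1.12 ± 0.20, MSMO1 at 0.92 ± 0.07 and DHCR7, the last enzyme of cholesterol synthesis, at 0.86 ± 0.15. The adjusted p values of these lists were 1.27e-10, 2.74e-07, 6.11e-05 and 2.88e-06, and with an estimated correlation the adjusted p was 0.473, 0.531, 0.646 and 0.115.

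Cytokines differed in both directions between the materials, with 9 of 24 higher with TiO2-NB and 3 higher with MWCNT, or 9 and 4 over the list alone. CXCL3 (-1.93 ± 0.15), CXCL5 (-1.71 ± 0.22) and CXCL2 (-1.50 ± 0.18) were lower with MWCNT. Of 17 NF-kappaB targets 7 were lower with MWCNT and 1 higher, or 9 and 1 over the list alone, with IRF1 at -0.83 ± 0.14. Of 28 lysosomal genes 10 were lower with MWCNT and 1 higher, also over the list alone, with NEU1 at -0.72 ± 0.07, and 7 of 19 autophagy genes were lower, also over the list alone, with ATG2A at -0.50 ± 0.11. Immediate early genes had 9 lower and 3 higher of 26, or 10 and 3 over the list alone, with NR4A3 at -2.01 ± 0.26. Ribosome biogenesis had 9 higher of 19, or 10 over the list alone, and oxidative phosphorylation had 4 higher and 1 lower of 27, also over the list alone. Camera called these 7 lists with adjusted p values of 0.0158, 0.0174, 0.00455, 0.0215, 0.00742, 0.00157 and 0.0336 in this order. With an estimated correlation the adjusted p was 0.187, 0.607, 0.115, 0.531, 0.489, 0.573 and 0.573, so none of the 11 called lists kept its call.

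Both exposures at 24 h were set against the same 3 control arrays, which by itself makes their changes alike. The log2 fold changes of MWCNT and TiO2-NB correlated across genes with r = 0.49, and 100 simulations without any effect of exposure gave 0.50 from the shared controls alone. The covariance was 0.0421 against 0.00741 in the simulations. In both exposures 331 genes were called higher and 216 lower, where independent calls would give 98.7 and 45.2. Independent calls leave out the shared controls. The simulations held no effect to call, which set their mean of 0.01 genes called in both beforehand. Neither tells how many shared calls the controls alone would add. A further 35 genes were called in opposite directions, 23 higher with MWCNT and 12 higher with TiO2-NB, where independent calls would give 145. The largest difference among them was that of FOXF1, at -0.95 with MWCNT and 1.34 with TiO2-NB. They also held NQO1, an NRF2 target, at -0.44 and 0.53, and NDRG1, a gene induced by hypoxia, at -0.40 and 0.42. With the 3 control arrays divided, 1 for 1 material and the other 2 for the other, r was from 0.25 to 0.51 over the 6 divisions, with a mean of 0.35 and a mean covariance of 0.0333. Equally numbered arrays of the 2 exposures also deviated together (r = 0.62, 0.44 and 0.36), so a preparation shared by them stays open.

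At 10 µg/ml few single genes passed the test at 24 h, while the cytokine list was higher with both materials. With MWCNT 0 genes were called by limma, 421 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.434. With TiO2-NB 2 genes were called and 474 had an unadjusted p under 0.05: ANKRD11 changed by -1.47 ± 0.20 (adjusted p = 0.000977) and TMEM50B (219600_s_at), a membrane protein, by -0.30 ± 0.05 (adjusted p = 0.024). When only the control and exposed arrays were fitted neither was called (adjusted p = 0.246 and 0.619, over all alternatives from 9.03e-05 to 0.246 and from 0.00517 to 0.619). TMEM50B was also lost without replicates 2 or 3 of the control and without replicates 2 or 3 of the exposed group (adjusted p from 0.165 to 0.272). The cytokine list had a median of 0.16 with MWCNT (adjusted p = 0.000184, adjusted p = 0.0258 with an estimated correlation) and 0.32 with TiO2-NB (adjusted p = 7.98e-12, adjusted p = 6.92e-05 with an estimated correlation). Adjusted over the list alone, 3 of its 24 genes rose with MWCNT and 6 with TiO2-NB. CXCL8 was at 0.11 ± 0.11 with MWCNT and 0.48 ± 0.11 with TiO2-NB, and neither was called over all genes.

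The NF-kappaB list was also called at 10 µg/ml and 24 h, with a median of 0.20 for MWCNT (adjusted p = 1.44e-08, adjusted p = 0.256 with an estimated correlation) and 0.16 for TiO2-NB (adjusted p = 2.5e-05, adjusted p = 0.509 with an estimated correlation). With MWCNT camera further called the interferon list (median 0.19), ribosome biogenesis (0.11), DNA replication (0.19), mitosis (0.17), LXR targets (0.16) and epithelial markers (-0.09), with adjusted p values of 2.25e-10, 0.000184, 0.00197, 0.00299, 0.00436 and 0.0119. No gene of these lists passed the test of limma over the list alone. With an estimated correlation their adjusted p was 0.561, 0.768, 0.997, 0.997, 0.805 and 0.401. The call of the epithelial markers was also lost with cyclic loess and without the 10 arrays that lay apart (adjusted p from 0.108 to 0.212, and from 0.00518 to 0.212 over the alternatives with the preset correlation). Between the materials at this dose and time 1 gene differed and 1033 had an unadjusted p under 0.05. It was ANKRD11, higher with MWCNT by 1.27 ± 0.20 (adjusted p = 0.0107). Its call was lost without replicates 1 or 3 of MWCNT or replicates 2 or 3 of TiO2-NB (adjusted p from 0.057 to 0.215). It was also lost when only these groups were fitted (adjusted p = 0.227, and from 0.00107 to 0.227 over all alternatives). With the replicate number as a block 4 genes differed.

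The doses were compared within each material to ask which genes responded to the higher dose beyond the lower. For MWCNT at 24 h 469 genes differed, 312 higher and 157 lower at 100 µg/ml. TNFAIP6 was higher by 1.94 ± 0.40, SPINK1, a trypsin inhibitor, by 1.92 ± 0.18 and the chemokine CCL19 by 1.75 ± 0.20. NPTX1 differed by -2.19 ± 0.28 and CYP1B1 by -1.79 ± 0.25. The count was 197 or 267 without replicates 1 or 2 at 10 µg/ml and 245 or 218 without replicates 2 or 3 at 100 µg/ml. For TiO2-NB at 24 h 1355 genes differed, 742 higher and 613 lower. CCR7 was higher by 2.82 ± 0.17, NR4A2 by 2.34 ± 0.47 and TNFAIP6 by 2.14 ± 0.40, while LBH, a transcription cofactor, differed by -1.45 ± 0.16 and GJA1 by -1.42 ± 0.29. The count was 874 without replicate 2 at 10 µg/ml and 710 when only these groups were fitted.

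At 1 h few genes were called against control. Limma called 0 genes with 10 or 100 µg/ml MWCNT and with 10 µg/ml TiO2-NB, and 162, 293 and 213 genes had an unadjusted p under 0.05. On simulated data with these spreads limma found 92%, 80% and 88% of genes changed 1.5-fold in these comparisons. The simulated spreads were independent between genes and arrays. On the real arrays 1 component took 43.1% of the variance around the group means at 1 h. The counts at an unadjusted p under 0.05 also lay below the 502.5 for no true change. The simulated shares may therefore not hold for the real arrays. Equally numbered arrays of the control and both MWCNT groups deviated together at 1 h, which the fit counted as spread. The counts of 0 with MWCNT may thus miss changes. With 100 µg/ml TiO2-NB 116 genes were called, 22 higher and 94 lower, with 1582 at an unadjusted p under 0.05. LIPT1 (205571_at), a lipoyltransferase, rose by 0.49 ± 0.07 and FBXL8 (220080_at), an F-box protein, by 0.51 ± 0.10. ZNF654 (219239_s_at), a zinc finger protein, changed by -0.75 ± 0.16 and USH1C (205137_x_at), a scaffold protein of hair cells, by -0.63 ± 0.12. LIPT1 lost its call without control replicate 2 (adjusted p = 0.0549), and FBXL8 without control replicates 1, 2 or 3 or TiO2-NB replicate 2 (adjusted p from 0.0522 to 0.0900). ZNF654 lost it without any 1 of the 6 arrays (adjusted p from 0.0561 to 0.161), and USH1C without control replicates 1 or 2 or TiO2-NB replicates 2 or 3 (adjusted p from 0.0683 to 0.0964). Only 7 of the 116 changed at least 1.5-fold, and 95 of them lay below the median level of all genes. The quartile range of the values was 3.64 ± 0.04 on these arrays and 3.51 ± 0.06 on the 1 h controls (SD, n = 3, exact permutation p = 0.1, two-sided and the smallest possible). The count was 0 when only these groups were fitted and without the 10 arrays that lay apart, 13 with the stricter filter, and 174 with median centring, of which 10 were higher. With the replicate number as a block it was 193, and in these 2 groups arrays of equal number deviated together (r = 0.61, 0.69 and 0.60). Leaving out 1 array gave 2 or 0 without control replicates 1 or 2, and 69, 21 or 12 without TiO2-NB replicates 1, 2 or 3.

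Against control at 1 h, list medians were at most 0.10 in size among the called lists. With 100 µg/ml TiO2-NB the epithelial markers had a median of -0.10 (adjusted p = 0.00181, adjusted p = 0.244 with an estimated correlation), with 2 of 16 lower, or 4 over the list alone. The mean log2 level of that list was 5.84, at percentile 20.8 of all genes. The lymphocyte markers had a median of -0.09 (adjusted p = 0.0489, adjusted p = 0.642 with an estimated correlation). Both calls were lost with cyclic loess, with adjusted p from 0.0612 to 0.134 for the epithelial and from 0.578 to 0.701 for the lymphocyte markers, and over the alternatives with the preset correlation it ranged from 0.000766 to 0.134 and from 0.0231 to 0.878. With MWCNT the oxidative phosphorylation list had a median of -0.03 at 100 µg/ml (adjusted p = 0.0258, adjusted p = 0.805 with an estimated correlation) and the p53 list -0.05 at 10 µg/ml (adjusted p = 0.0382, adjusted p = 0.208 with an estimated correlation). Both were lost with cyclic loess and in 2 further alternatives each, with adjusted p over the alternatives with the preset correlation from 0.00166 to 0.205 and from 0.0164 to 0.452. With the replicate number as a block the metallothionein list was also called for 100 µg/ml MWCNT (median -0.11, adjusted p = 0.0360). HMOX1, the antioxidant gene, was at -0.04 ± 0.11 with 10 µg/ml MWCNT.

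Between the materials at 1 h limma called 0 genes at 10 µg/ml, with 264 at an unadjusted p under 0.05. At 100 µg/ml 143 genes differed, 114 higher and 29 lower with MWCNT. HOXD1, a homeobox factor, was higher with MWCNT by 0.71 ± 0.12 and ANGPTL4, a lipase inhibitor, differed by -0.63 ± 0.13. HOXD1 lost its call without MWCNT replicate 2 or TiO2-NB replicate 3 (adjusted p = 0.0521 and 0.0565), and ANGPTL4 without MWCNT replicate 1 or TiO2-NB replicates 2 or 3 (adjusted p from 0.0604 to 0.0867). The count was 76, 10 or 59 without MWCNT replicates 1, 2 or 3 and 6 or 18 without TiO2-NB replicates 2 or 3. It was 0 with the stricter filter or when only these groups were fitted, and 86 with median centring, of which 79 were higher. Oxidative phosphorylation (median -0.06, adjusted p = 0.00742), epithelial markers (0.13, adjusted p = 0.00742) and autophagy (-0.08, adjusted p = 0.0313) were called, and none kept its call (adjusted p = 0.531, 0.329 and 0.531 with an estimated correlation). Between the doses at 1 h limma called 0 genes for MWCNT, with 292 at an unadjusted p under 0.05, and 8 for TiO2-NB. GDF5, a bone growth factor, differed by -0.60 ± 0.08 (adjusted p = 0.0015, and from 0.000651 to 0.418 over all alternatives). The 8 became 1, 1 and 90 without replicates 1, 2 and 3 at 10 µg/ml, and 4 and 3 without replicates 2 and 3 at 100 µg/ml. They became 0 when only these groups were fitted.

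The control cells themselves changed over the day between the times, with 3708 genes called, 2087 higher and 1621 lower at 24 h. With cyclic loess over the tested probe sets alone 1782 of 3671 called genes were higher. MMP12 (204580_at), the macrophage elastase, rose by 4.40 ± 0.33, LBH (221011_s_at) by 3.74 ± 0.16 and CEMIP (212942_s_at) by 3.39 ± 0.27. TSC22D3 (208763_s_at), a glucocorticoid-induced factor, changed by -3.80 ± 0.12, KLF2 (219371_s_at) by -3.76 ± 0.25, and HMMR (207165_at), a mitotic spindle protein, by -3.17 ± 0.19. All 27 mitosis genes fell, with a median of -2.33 (adjusted p = 1.62e-30, adjusted p = 0.0438 with an estimated correlation). Of 18 cholesterol genes 17 fell, with a median of -1.38, such as ACAT2 (-2.90 ± 0.17) and HMGCS1 (-2.11 ± 0.11), enzymes at the start of sterol synthesis (adjusted p = 2.44e-21, adjusted p = 6.41e-05 with an estimated correlation). Of 26 NRF2 targets 18 fell and 2 rose, with SLC7A11 at -2.13 ± 0.25 and GCLM at -2.03 ± 0.19 (adjusted p = 2.71e-09, adjusted p = 0.0438 with an estimated correlation). Each of these 3 counts was the same over the list alone.

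Further lists moved with culture time but lost their call with an estimated correlation. Of 28 interferon-stimulated genes 25 fell and 1 rose (median -0.99, with MX1 at -2.25 ± 0.22), and 20 of 23 DNA replication genes fell (median -0.82, 21 over the list alone). Of 16 promonocyte and monocyte markers 10 fell and 2 rose (median -0.93), led by the granule proteases CTSG (-2.98 ± 0.36) and ELANE (-2.49 ± 0.43). Of 7 metallothioneins and zinc exporters 6 fell, or 7 over the list alone, and 8 of 19 autophagy genes fell while 1 rose. Scavenger receptors had 13 of 22 higher and 2 lower (MSR1 at 2.61 ± 0.21, CD163 at 2.17 ± 0.15), and matrix genes 13 of 21 higher and 2 lower, or 14 and 3 over the list alone (MMP10, a stromelysin, at 2.05 ± 0.33). The adjusted p with an estimated correlation was 0.0786 for the interferon and the monocyte lists, 0.304 for replication and metallothioneins, 0.312 for autophagy, 0.118 for scavenger receptors and 0.0537 for matrix genes. With the residual components as covariates it was 0.0313 for replication, 0.0253 for the monocyte list, 0.0416 for scavenger receptors and 0.00784 for matrix genes, which then kept their call, and 0.0694 for interferon, 0.265 for metallothioneins and 0.288 for autophagy, which did not. IL1B rose by 1.06 ± 0.20, ABCG1, a cholesterol exporter, by 1.49 ± 0.32 and CDKN1A by 0.58 ± 0.10, and HMOX1 changed by -0.64 ± 0.11.

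Whether the response to 100 µg/ml differed between 24 h and 1 h was tested within each material. For MWCNT it differed for 373 genes, 265 of them with a more positive change at 24 h, such as TNFAIP6 (2.79 ± 0.57), CCL4 (2.43 ± 0.32) and VCAM1 (2.27 ± 0.35), while NPTX1 was at -3.19 ± 0.39. The count was 193 without replicate 1 of the 1 h control, 227 or 229 without replicates 2 or 3 of MWCNT at 1 h, 173 without replicate 1 of the 24 h control, 240 without replicate 2 of MWCNT at 24 h, and 152 when only these groups were fitted. For TiO2-NB it differed for 1642 genes, 753 more positive and 889 more negative at 24 h, such as CCR7 (3.52 ± 0.24), CCL4 (2.54 ± 0.32) and CXCL1 (2.53 ± 0.32), with LBH at -1.95 ± 0.23. With median centring 1175 of 1729 were more positive, the count was 1077 without replicate 2 of the 24 h control, and 1019 when only these groups were fitted. Tested over all 4 exposures together, 87 genes (0.866%) changed at 1 h and 2936 (29.2%) at 24 h. The 87 became 52 without replicate 1 of the control, 34 or 3 without MWCNT 10 µg/ml replicates 1 or 2, 57 or 147 without TiO2-NB 10 µg/ml replicates 2 or 3, and 19, 4 or 0 without TiO2-NB 100 µg/ml replicates 1, 2 or 3.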

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

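The difference between the responses at both times, the test of an early start, the tests of the change over culture and the splits were set before their results were seen, while the tests by cyclic loess, by shared preparation and by RNA degradation, and the sorting of the splits by which groups they kept, were chosen after it.

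The response to 100 µg/ml differed between 24 h and 1 h in a test of the difference itself. For MWCNT 373 genes differed, among them TNFAIP6 (2.79 ± 0.57, adjusted p = 0.00671 by limma), CCL4 (2.43 ± 0.32, adjusted p = 0.000113), NPTX1 (-3.19 ± 0.39, adjusted p = 7.35e-05) and MMP12 (-1.73 ± 0.47, adjusted p = 0.0387). MMP12, the macrophage elastase, was not called without replicates 1, 2 or 3 of the 1 h control, replicates 1 or 2 of the 24 h control, replicates 1 or 2 of MWCNT at 1 h or replicates 1 or 3 of MWCNT at 24 h (adjusted p from 0.0528 to 0.123), and its range over all alternatives was from 5.52e-05 to 0.123. For TiO2-NB 1642 genes differed, among them CCR7 (3.52 ± 0.24, adjusted p = 1.34e-09), CCL4 (2.54 ± 0.32, adjusted p = 1.29e-05), LBH (-1.95 ± 0.23, adjusted p = 3.77e-06) and THSD7A (-1.89 ± 0.48, adjusted p = 0.00982). Of 100 splits that exchanged the arrays, 7 gave at least as many genes as the real one for MWCNT, with 810 as the highest other value, so chance is not excluded for that count. For TiO2-NB only the real split, 1 of 100, did, with 1591 as the highest other value, but this does not exclude chance in the difference between the times. These counts rest on the grouping at 24 h: the 11 other MWCNT splits that kept the 24 h groups called 318 to 810 genes and the 88 that did not called 0 to 1, and for TiO2-NB the 8 that kept them called 857 to 1591 and the 91 that did not 0 to 58. The splits that reached the real MWCNT count are all among those that kept its 24 h groups, so they still hold the effect at 24 h and do not speak for chance in it. For either material these counts say little about chance in the difference between the times, and the 6 arrays at 24 h alone make 10 splits, too few for a share under 0.05.

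With 100 µg/ml TiO2-NB at 1 h 95 of the 116 called genes (81.9%) lay below the median level of all genes, and 88 of these were among the 94 lower genes. Of the called genes 22.4% had the same direction at 24 h, where random lists matched on expression had a median of 41.4% (percentile 0.01 of 10000 lists). By the rule set beforehand this goes against an early start of the 24 h response. However, in the lowest and second lowest of 10 groups of genes by level the median change was -0.08 and -0.09 at 1 h. At 24 h it was 0.06 and 0.04. Such opposite shifts of dim genes may by themselves lower the share, so an early start stays open. Whether a different spread of the values on these arrays made the change of these genes could not be decided by cyclic loess. It removes only a shift common to genes of 1 level. That shift was too small to be the whole of changes chosen for their size. Over 10 groups of genes by level the median change lay between -0.09 and 0.09, and between -0.04 and 0.03 after cyclic loess over all kept probe sets or over the tested ones alone. The median change of the lower genes went from -0.44 to -0.41 and -0.39 (median standard error 0.0997, 0.0974 and 0.0960), and that of the higher genes from 0.32 to 0.25 with both forms (0.0684, 0.0662 and 0.0685). How far the spread made the number of calls stays open: 72 and 40 genes were called, of which 83.3% and 75% lay below the median level, and of the 94 lower genes 58 and 29 kept their call and of the 22 higher genes 7 and 6. These medians, over all called genes of a direction, became smaller with about equal standard errors, and why the other calls ended was not tested. These genes were chosen by their change, so its size may be too high in every form.

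In each group 1 array stood apart from the other 2 on the first component of the values around the group means. That 1 array lies opposite the other 2 is set beforehand, since deviations from a group mean cancel out. Only the size of the scores and the direction shared by the groups of a time are not set by this. It was replicate 2 at 1 h except for replicate 1 of 10 µg/ml TiO2-NB, and at 24 h replicate 3 of the control and both 10 µg/ml groups and replicate 1 of both 100 µg/ml groups. RNA degradation at 1 h that acts alike on GAPDH and actin is argued against. The 3-prime minus 5-prime difference followed the component in opposite directions for GAPDH (r = 0.85, adjusted permutation p = 0.00016) and for actin (r = -0.67, adjusted permutation p = 0.0156). By ranks the directions were also opposite (0.84, permutation p = 0.00018, and -0.51), but that of actin missed the threshold (permutation p = 0.0569). At 1 h GAPDH explained 71.5% of the component's variance (95% bootstrap interval 49.0% to 93.9%) and actin 45.3% (20.1% to 81.7%). Judged by these shares, as at 24 h, RNA degradation at 1 h would stay open. At 24 h RNA degradation stays open, with 28.5% of the component's variance explained by GAPDH (95% bootstrap interval 9.06% to 64.1%) and 8.61% by actin (0.0193% to 29.3%). A set of cultures or preparations shared by both times also stays open, with r = 0.23 between the gene weights at 1 h and 24 h, and no biological explanation was tested.

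Genes that changed over a day of culture tended to move the other way with 100 µg/ml at 24 h: 505 of 747 genes called in both (67.6%) for MWCNT and 936 of 1252 (74.8%) for TiO2-NB. With the culture change taken from the 10 µg/ml TiO2-NB groups, MWCNT showed this only for genes that fell over culture. Of these 1567 genes 63.9% were higher with MWCNT, against 47.0% of all genes, while genes that rose over culture did not differ from all genes. That the arrays of the 24 h control, shared by both contrasts, alone made this pattern is argued against, since the correlation was -0.28 for MWCNT and -0.30 for TiO2-NB with a culture change taken from groups that share no array, and -0.33 and -0.34 with the own controls. By ranks it was -0.15 for MWCNT, which is weaker and short of the bound set beforehand for the correlation, and -0.30 for TiO2-NB. The 10 µg/ml arrays that gave this culture change deviated together with the 24 h control arrays of equal number (r from 0.40 to 0.68 for MWCNT and from 0.11 to 0.65 for TiO2-NB), so a preparation shared by these groups stays open. Cell cycle genes alone are argued against for TiO2-NB, where 65.1% of 2456 genes that rose over culture were lower under exposure, against 47.1% of all genes. For MWCNT they stay open, with 53.1% of 1859 such genes against 53% of all genes, although without the genes of the cell cycle lists the correlation was still -0.24. Those lists do not hold every cell cycle gene. A slower change of the exposed cells over culture, or fewer cells changing, may lie behind the part that is not cell cycle, and neither was tested.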

How the results depend on the processing

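Cyclic loess in 2 forms, the residual components as covariates and the fit without the 10 arrays that stood apart were chosen after seeing the data, and the other alternatives before. No named gene or list changed its direction where it was called. The side with more genes did turn for some counts. With median centring 1267 of 2233 genes were higher for 100 µg/ml TiO2-NB at 24 h (1099 of 2219 without), 1010 of 2776 for the materials at 100 µg/ml and 24 h (1411 of 2505) and 1175 of 1729 for the TiO2-NB responses at both times (753 of 1642). With cyclic loess it turned for the last of these (814 of 1557), and over the tested probe sets alone for control time (1782 of 3671, 2087 of 3708 without). For 100 µg/ml TiO2-NB at 24 h it also turned without a filter (1086 of 2159) and without replicate 2 of the control or of TiO2-NB (937 of 1775 and 974 of 1917), for 100 µg/ml TiO2-NB at 1 h with the residual components (281 of 533, 22 of 116 without), and for the materials at 100 µg/ml and 1 h without replicate 2 of MWCNT (4 of 10, 114 of 143 with it) or without the 10 arrays (0 of 1). For 10 µg/ml TiO2-NB at 24 h (0 of 2) it turned with the components (12 of 16) and without the 10 arrays (4 of 5). Where a count moved by more than 1.5 times the cause was not tested, except where stated.

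With no filter on dim probe sets every count stayed within 1.5 times. With the stricter filter, which tests fewer genes, 100 µg/ml TiO2-NB at 1 h had 13, the materials at 100 µg/ml and 1 h 0, the TiO2-NB doses at 1 h 0 and any exposure at 1 h 8. The block gave 193 for 100 µg/ml TiO2-NB at 1 h and 4 for the materials at 10 µg/ml and 24 h. With only the groups compared, which leaves fewer arrays to estimate the spread, the count was 0 for 100 µg/ml TiO2-NB at 1 h, for 10 µg/ml TiO2-NB at 24 h, for the materials at 100 µg/ml and 1 h and at 10 µg/ml and 24 h, for the TiO2-NB doses at 1 h and for any exposure at 1 h. It was 1304 for 100 µg/ml TiO2-NB at 24 h, 710 for its doses at 24 h, and 152 (MWCNT) and 1019 (TiO2-NB) for the responses at both times. Centring gave 1 for 10 µg/ml TiO2-NB at 24 h, 86 and 2 for the materials at 100 µg/ml and 1 h and at 10 µg/ml and 24 h, and 17 for the TiO2-NB doses at 1 h. Trend and robust prior gave 60 for 100 µg/ml TiO2-NB at 1 h, 1 for 10 µg/ml TiO2-NB at 24 h and 41 for any exposure at 1 h. Every probe set gave 15 for 10 µg/ml TiO2-NB at 24 h and 2 for the materials at 10 µg/ml and 24 h. Cyclic loess gave 72 for 100 µg/ml TiO2-NB at 1 h, and over the tested probe sets alone 40, with 4 for the TiO2-NB doses and 47 for any exposure at 1 h.

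The residual components as covariates come from the same residuals that measure the spread, so counts run high. At 1 h they gave 1 for 100 µg/ml MWCNT, 533 for 100 µg/ml TiO2-NB, 452 for the materials at 100 µg/ml, 26 for the TiO2-NB doses and 277 for any exposure. At 24 h they gave 8 and 2487 for 10 and 100 µg/ml MWCNT, 16 and 3354 for TiO2-NB, 24 for the materials at 10 µg/ml, 1373 (MWCNT) and 2454 (TiO2-NB) for the doses and 4661 for any exposure, and 1250 and 3002 for the responses at both times. The 10 arrays that stood apart were also chosen by these residuals. Leaving them out can lower the measured spread, so rises of a count are no sign of robustness, while fewer arrays are left. Without the 10 arrays counts at 1 h were 1 for 100 µg/ml MWCNT, 0 for 100 µg/ml TiO2-NB, 1 for the materials at 100 µg/ml, 0 for the TiO2-NB doses and 1 for any exposure. At 24 h they were 4 for 10 µg/ml MWCNT, 5 for 10 µg/ml TiO2-NB, 0 for the materials at 10 µg/ml, 726 for the MWCNT doses and 656 for its responses at both times.

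Leaving out 1 array gave 0 to 103 genes for 100 µg/ml TiO2-NB at 1 h, 778 to 1288 for 100 µg/ml MWCNT and 1775 to 1917 for 100 µg/ml TiO2-NB at 24 h, and 1 to 3 for 10 µg/ml TiO2-NB at 24 h. It gave 6 to 127 for the materials at 100 µg/ml and 1 h, and 0 to 1 and 1797 to 2325 at 10 and 100 µg/ml and 24 h. The doses gave 1 to 90 (TiO2-NB, 1 h), 197 to 411 (MWCNT, 24 h) and 874 to 1171 (TiO2-NB, 24 h), control time 3147 to 3420, the responses at both times 173 to 483 (MWCNT) and 1077 to 1730 (TiO2-NB), and any exposure 0 to 147 at 1 h and 2369 to 2957 at 24 h. The comparisons with a count of 0 stayed at 0.

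Of 498 named results past the threshold 140 lost it without some array, 109 with only the groups compared, 79 without the 10 arrays, 34 with centring, 33 with the mean of all probe sets, 26 and 19 with the forms of cyclic loess, 14 without a filter, 10 with the trend, 8 with the block and 0 with the covariates, and 8 of 438 with the stricter filter. Of 208 list tests of exposure 30 were called, and 26 of these 30 lost the call with the estimated correlation and 21 with that and the residual components. Between the materials all 14 called lists lost it with either, and for control time 7 and 3 of 10.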

Other observations

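The gene groups for dendritic cell maturation and for the aryl hydrocarbon receptor were chosen after the values were seen, and the splits were set before, while their relation to the residual component was tested after they were seen.

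Several genes of dendritic cell maturation rose after 24 h with 100 µg/ml. Of 21 such genes 18 were measured, 5 rose with MWCNT, 6 rose and 1 fell with TiO2-NB, and 6 differed between the materials. CCR7 was at 1.65 ± 0.17 with MWCNT and 3.37 ± 0.17 with TiO2-NB, LAMP3 at 2.31 ± 0.28 and 1.99 ± 0.28, CD83 at 0.39 ± 0.06 and 0.90 ± 0.06, and CCL19 at 1.67 ± 0.20 and 0.13 ± 0.20. The log2 levels of CCR7, LAMP3 and CCL19 lay below the median level of all genes. The gene that fell with TiO2-NB was FSCN1, at -0.17 ± 0.12 with MWCNT and -0.44 ± 0.12 with TiO2-NB. CD86, CCL17, CCL22, CD1A, CD1C, MARCKSL1, SLAMF1, HLA-DRA, HLA-DMB and CIITA were not called with either material. Of 8 targets of the aryl hydrocarbon receptor 7 were measured, 3 fell with MWCNT, 3 rose with TiO2-NB, and 4 differed between the materials. CYP1B1 was at -2.44 ± 0.25 and 0.13 ± 0.25, TIPARP at -1.08 ± 0.20 and 0.82 ± 0.20 and NQO1 at -0.44 ± 0.09 and 0.53 ± 0.09. The other gene that rose with TiO2-NB was NFE2L2, which codes for NRF2 (0.63 ± 0.10), and NQO1 is also an NRF2 target. CYP1A1 was not called with either material (-0.09 ± 0.11 and 0.11 ± 0.11). Its log2 level was 4.97, where the median level of all genes was 7.56.

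For every comparison of 3 with 3 arrays the 6 arrays make 10 splits, which are too few for a share under 0.05. In the comparisons with a count of 0 by limma all 10 splits gave as many, which a real count of 0 sets beforehand, and the highest other count was 0, or 1 for the MWCNT doses at 1 h. These were MWCNT at both doses and 10 µg/ml TiO2-NB at 1 h (162, 293 and 213 genes at an unadjusted p under 0.05), 10 µg/ml MWCNT at 24 h (421), the materials at 10 µg/ml and 1 h (264) and the MWCNT doses at 1 h (292). In the other comparisons only the real split, 1 of 10, gave as many. The real and the highest other count were 116 and 0 for 100 µg/ml TiO2-NB at 1 h, 1309 and 0 for 100 µg/ml MWCNT, 2 and 0 for 10 µg/ml TiO2-NB and 2219 and 0 for 100 µg/ml TiO2-NB at 24 h. For the materials they were 143 and 1 (100 µg/ml, 1 h), 1 and 0 (10 µg/ml, 24 h) and 2505 and 2 (100 µg/ml, 24 h). For the doses they were 8 and 0 (TiO2-NB, 1 h), 469 and 0 (MWCNT, 24 h) and 1355 and 0 (TiO2-NB, 24 h), and for the control times 3708 and 1. Where arrays of equal number deviated together, as for the materials at 100 µg/ml and 1 h or 24 h, the 3 other splits that part all 3 such pairs gave 0, and the counts of 1 and 2 came from splits that part 1 pair. For 100 µg/ml TiO2-NB at 1 h both kinds of split gave 0. For any exposure at 1 h 7 of 100 splits gave at least the real 87 genes, with 971 as the highest, so chance is not excluded. The split that called 971 points to a structure of the samples: its groups took 72.2% of the variance of the first residual component at 1 h, the 3rd highest share of 99 other splits, whose median was 23.4%, and over these splits the count and the share had a rank correlation of 0.39. For any exposure at 24 h only 1 of 100 splits, the real one, gave as many as 2936 genes, with 1076 as the highest other. That is the smallest share that 100 splits can give, and it argues against chance if the arrays are independent. Equally numbered arrays at 24 h in part deviated together, which a free exchange of arrays ignores. A preparation shared by arrays is therefore not excluded. At 24 h the component did not mark the highest split in this way: the groups of the split with 1076 took 18.2% of its variance, below the median of 21.4%, and the rank correlation was 0.23.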
